A study of Arabidopsis thaliana with 72 samples.

How the data were processed

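Arabidopsis thaliana seedlings were grown for 14 days under 16 h of light and 8 h of dark, and were treated 7 h after lights on with 8 mL of 21 μM t-chalcone per plate of 24 seeds, or with 0.1% ethanol (EtOH) as the control, per the labels and their protocols. The solvent of t-chalcone is not given in the sources used here. Shoots and roots were sampled at 0 h (untreated or with EtOH) and at 1, 3, 6, 12 and 24 h (t-chalcone or EtOH), with 3 samples in each of 24 groups of tissue, treatment and time. Replicate numbers were given in accession order and only name a library.

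The deposited table held 22884 genes and 72 columns with no value of 0. Its values have the unit of a signal, namely gene counts that the authors divided by size factors with DESeq2 1.14.1 against TAIR10, per the submitters' processing notes. The aligner and the counter are not given in the sources used here, nor is whether counting used strand, so reads of a gene and an overlapping antisense gene cannot be told apart. Near-identical copies, such as the light-harvesting genes CAB2, LHCB2.1 and LHCB2.2, the terpene synthase pair that both carry the symbol TPS-CIN or neighbouring GSTU genes, may share reads, and values of single members are uncertain to that extent. In each column 100.0% of values were whole multiples of the column's lowest value within 0.01, so whole numbers could be recovered from the deposited signal. The division matched median-of-ratios size factors over all 72 columns to a relative difference of 1.2e-09. No recovered whole number was 0. In 29 shoot libraries at least 7 of the whole numbers from 2 to 99 never occurred, as if 1 plus a count had been multiplied by a factor above 1 and rounded. The factors estimated under that reading were 0.704 to 1.33 in shoots and 0.652 to 0.974 in roots. Of the libraries with a factor under 1, shoots EtOH 12 h replicate 2 and roots EtOH 3 h replicate 1, both under 0.5 M, lacked 1 and 4 of these numbers, and the others lacked none. This is a reading of the values, and neither the labels nor the notes state such a step. The recovered whole numbers therefore follow read counts only up to a factor per library, and tests on them treat counting error as slightly larger or smaller than it was.

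The 6 columns of untreated seedlings at 0 h were identical to the 6 of EtOH at 0 h, in every gene. Each pair was counted as 1 library, under the EtOH group, which left 66 libraries in 22 groups of 3. The intended comparison of EtOH with untreated seedlings could not be made, and the fits held 33 libraries in 11 groups per tissue where 36 and 12 had been intended. Depth was taken from the recovered whole numbers, whose totals in M (mega) were 0.246 to 26.0 M in shoots and 0.128 to 22.5 M in roots. In libraries under 0.5 M the lowest value itself stood as high as 40.5 deposited units, so a low gene there cannot be told from one without reads. Descriptions of 7 libraries carried an S number where the others had an index sequence, which was treated as a possible library batch. The reference was the TAIR10.1 assembly, used only for names: 22708 of the identifiers were in it and 9607 had a symbol, and no coordinates are printed because the deposited table names another release. Genes of the mitochondrial genome numbered 78 and took 0.001% to 0.538% of shoot totals, and no chloroplast gene was in the table.

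The test was limma with a mean-variance trend on log2(deposited value + 1), fitted per tissue with 1 mean per group over all 33 libraries, after keeping genes with a value of at least 10 in at least 3 libraries (22884 genes in shoots, 19835 in roots). In shoots this removed no gene, since the lowest values of 3 libraries under 0.5 M lie above 10. P-values were two-sided and adjusted by Benjamini and Hochberg over all genes kept, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes, and each ± beside a fold change is limma's standard error. Contrasts were t-chalcone minus EtOH at each time, differences of that effect between tissues in a fit of all 66 libraries, and F tests for differences of the effect between times and of EtOH libraries from 0 h. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within each comparison, and with an estimated correlation as an alternative.

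The 28 lists held 531 distinct genes, of which 4 were not in the table used here. They covered glutathione transferases, detoxification, sulfur assimilation, heat shock, endoplasmic reticulum stress, redox, proteasome, flavonoid, phenylpropanoid, auxin, auxin transport, cytokinin, abscisic acid, jasmonate, salicylic acid, ethylene, camalexin, glucosinolate, cell cycle, nucleolus, photosynthesis, chlorophyll, circadian clock, starvation, cell wall, root hair, root marker and iron genes. The lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined. Added afterwards were the comparison of libraries by similarity, 5 tests on clock or photosynthesis genes, 1 on the size of changes in thinned libraries, and 3 alternatives: leaving out the 5 libraries under 0.5 M, a filter that also asks for a value above the library's lowest, and edgeR without those 5 libraries. Genes were named by rule. Per comparison these were the 6 largest increases and the 6 largest decreases among genes past the threshold with a symbol, a mean of at least 50 in the higher group and no overlap between the 3 t-chalcone and the 3 EtOH libraries. Per list with a camera adjusted p under 0.05 or at least 3 called members, up to 3 called members in the main direction and 1 in the other were added. GSTU24, CYP81D8, UGT74E2, chalcone synthase (symbol TT4), HSP70, GH3.3, AOX1A and APR1 were followed in every comparison. For differences between tissues the rule took the 3 largest of each sign, and for times in controls the clock list.

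The alternatives set beforehand were a pseudocount of 0.5 or 4, no filter or a filter of 50, TMM or median-of-ratios scaling within the tissue, only the groups of the contrast, array weights, a term for the S number, leaving out the S-number libraries, leaving out each library in turn, and edgeR's quasi-likelihood test and DESeq2 on the recovered whole numbers. The analysis used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The fits were tested on simulated data drawn from the real means, spreads and library sizes with 200 changed genes per tissue. Over the 5 times, limma recovered 40% to 54% of 2-fold and 86% to 94% of 4-fold changes, with up to 33 other genes called, and edgeR recovered 46% to 94% and 89% to 99%. Camera gave a list of 20 genes raised in the tissue p-values of 1.32e-47 or lower in shoots and 2.25e-37 or lower in roots, and 20 genes changed in the other tissue alone p-values from 0.0465 to 0.919 in shoots and 0.383 to 0.876 in roots. For differences between tissues limma recovered 16% to 26% of 2-fold and 74.5% to 80.5% of 4-fold changes, with up to 40 other genes called (37 at 3 h and 40 at 24 h).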

Results

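RNA sequencing was used to measure transcript levels in shoots and roots of 14-day-old Arabidopsis thaliana seedlings given 21 μM t-chalcone, an aromatic ketone with the carbon skeleton from which flavonoids are built, or 0.1% ethanol (EtOH) as the control. Samples were taken at the start (0 h) and 1, 3, 6, 12 or 24 h later, with 3 libraries per group of tissue, treatment and time. The 72 deposited columns included 6 of untreated seedlings whose values were identical to those of EtOH at 0 h, so each such pair was counted as 1 library and 66 libraries remained. What EtOH itself did at 0 h therefore could not be tested. The labels do not say that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

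The whole numbers recovered from the deposited values, in M (mega), summed to between 0.246 and 26.0 M per library in shoots (median 14.5 M) and to between 0.128 and 22.5 M in roots (median 10.3 M). A total under 0.5 M was found for 5 libraries, namely roots EtOH 0 h replicate 1 (0.186 M), roots EtOH 3 h replicate 1 (0.128 M), shoots EtOH 12 h replicate 2 (0.246 M), shoots EtOH 24 h replicate 3 (0.327 M) and shoots t-chalcone 24 h replicate 2 (0.39 M). In these 5, between 33.0% and 77.8% of genes stood at the library's lowest value, against at most 20% in every other library. Photosynthesis genes averaged 12.65 to 14.89 on the log2 scale in shoot libraries and 5.41 to 8.60 in root libraries. Root marker genes averaged 3.28 to 6.19 in shoots and 7.27 to 8.45 in roots, so both lists separated the tissues as labelled.

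**Figure D1:**
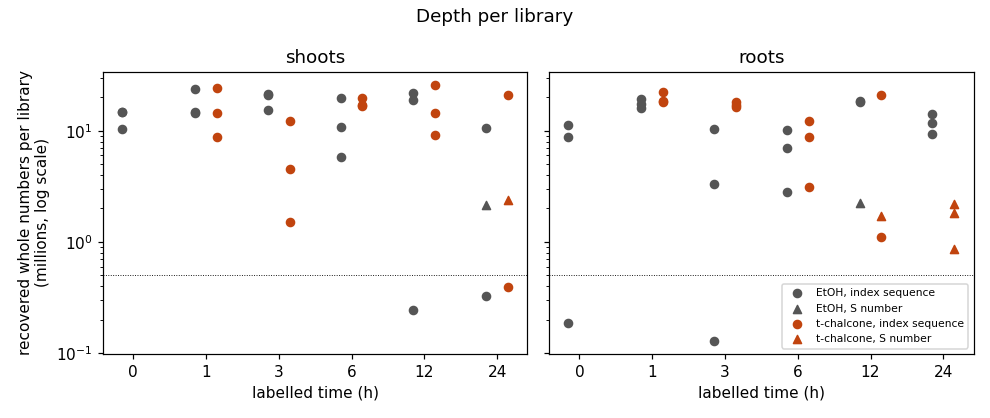
Total of recovered whole numbers per library in M (log axis) for each group of tissue, treatment and time; triangles mark libraries whose description carries an S number and the dotted line marks 0.5 M. The 5 libraries under the line range from 0.128 to 0.39 M, and the 3 t-chalcone root libraries at 24 h hold 0.866, 1.83 and 2.19 M against 9.30 to 14.3 M in their controls.

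The series compared t-chalcone with EtOH at each time in each tissue. With limma, roots had 914 genes past an adjusted p of 0.05 at 1 h, 2688 at 3 h, 89 at 6 h, 6 at 12 h and 378 at 24 h, of 19835 tested. Shoots had 11, 8, 355, 174 and 262 of 22884 tested at the same times. Below, changes are log2 fold changes of t-chalcone over EtOH ± standard error, and levels are means ± SD of the deposited values (n = 3 per group). The genes named for the size of their change had a symbol, a mean of at least 50 in the higher group and all 3 t-chalcone libraries on one side of all 3 controls, so larger changes can stand among other genes. Chance gives that last arrangement for 10% of genes, and it was seen for 13.1% to 37.9% of genes in the 10 comparisons. The median change over all genes was 0.145 in roots at 3 h and -0.155 at 24 h. Scaling by trimmed mean of M-values (TMM) moved it to 0.03 in roots at 3 h and from 0.09 to 0.20 in shoots at 12 h. No gene list that passed its test turned its direction under TMM or median-of-ratios scaling within the tissue.

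**Figure D2:**
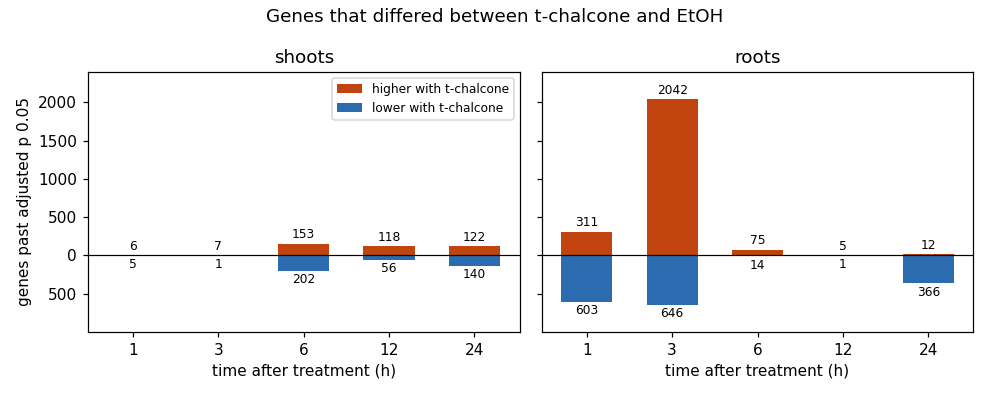
Number of genes higher (bars above 0) and lower (bars below 0) in t-chalcone than in EtOH libraries at each time (x axis, h) at a limma adjusted p under 0.05. Roots reach 2042 higher and 646 lower at 3 h, and 24 h stands out with 12 higher against 366 lower.

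In roots at 1 h, small heat shock proteins gave the largest increases. HSP17.4 (AT3G46230) rose from 6.16 ± 1.55 to 208 ± 145 (4.68 ± 0.44, adjusted p = 6.55e-09), and HSP17.6A (AT5G12030) and HSP17.6II (AT5G12020) rose by 4.43 ± 0.56 and 4.23 ± 0.66. Genes for conjugation or export of foreign compounds rose with them. Among these were the glutathione transferases GSTU11 (AT1G69930, 3.3 ± 0.48) and GSTU24 (AT1G17170, 507 ± 61.2 to 3720 ± 633, 2.87 ± 0.23, adjusted p = 2.78e-10). The ABC transporter ABCG40 (AT1G15520, 2.97 ± 0.39), the glycosyltransferases UGT75B1 (AT1G05560, 2.92 ± 0.34) and UGT74E2 (AT1G05680, 2.80 ± 0.24), and the cytochrome P450 CYP81D8 (AT4G37370, 2.22 ± 0.28) belonged to them as well. The largest decrease was in NRT2:1 (AT1G08090), a high-affinity nitrate transporter (94.3 ± 36.9 to 4.08 ± 1.71, -4.20 ± 0.44, adjusted p = 7.71e-08). The beta-glucosidases BGLU34 (AT1G47600, -3.25 ± 0.45) and BGLU35 (AT1G51470, -3.15 ± 0.41), the wall-modifying XTH12 (AT5G57530, -3.16 ± 0.41), the extensin EXT6 (AT2G24980, -2.84 ± 0.41) and the metal reductase FRO4 (AT5G23980, -2.79 ± 0.23) fell as well.

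Of 24 detoxification genes measured in roots at 1 h, 15 rose and 9 did not pass (17 adjusted over the list alone), and camera gave the list an adjusted p of 2.4e-39. Of 24 heat shock genes, 15 rose and 9 did not pass (16 adjusted over the list alone, camera adjusted p = 8.9e-33), among them HSP70 (AT3G12580), a chaperone of the heat response (2.55 ± 0.45). Of 10 root hair genes, 9 fell and 1 did not pass (9 adjusted over the list alone, camera adjusted p = 1.12e-21), with PRP1 (AT1G54970) at -2.64 ± 0.36, PRP3 (AT3G62680) at -2.23 ± 0.33 and RHS19 (AT5G67400) at -2.14 ± 0.29. Of 12 root marker genes, 4 fell, including NRT2:1, PRP3 and SHV2 (AT5G49270, -1.76 ± 0.28), and 8 did not pass (4 adjusted over the list alone, camera adjusted p = 3.22e-05). These 4 lists passed with an estimated correlation too. Glutathione transferases went both ways, with 11 of 39 higher, 4 lower, among them GSTU28 (AT1G53680, -1.19 ± 0.23), and 24 not past the test (18 adjusted over the list alone). Their median was -0.17 and their mean 0.37, so that median and test differed in sign (camera adjusted p = 0.000423, adjusted p = 0.334 with an estimated correlation).

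Sulfur assimilation genes rose in 5 of 20 cases, led by BGLU28 (AT2G44460, 4.04 ± 0.87), LSU1 (AT3G49580, 1.87 ± 0.28) and APR3 (AT4G21990, 1.67 ± 0.21), while the sulfate transporter SULTR1;1 (AT4G08620) fell (-1.80 ± 0.43) and 14 did not pass (8 adjusted over the list alone). Of 18 abscisic acid genes, 4 rose, including NCED3 (AT3G14440), which makes the precursor of the hormone (1.88 ± 0.35), 1 fell and 13 did not pass (10 adjusted over the list alone). Camera adjusted p-values were 1.53e-06 and 4.34e-06 for these lists, and adjusted p = 0.176 and adjusted p = 0.092 with an estimated correlation. Of 11 glucosinolate genes, 4 fell and 7 did not pass (9 adjusted over the list alone, camera adjusted p = 1.64e-08, adjusted p = 0.0968 with an estimated correlation). Among 19 phenylpropanoid genes, 3 fell, including FAH1 (AT4G36220, -2.42 ± 0.24) and OMT1 (AT5G54160, -1.23 ± 0.15), and 16 did not (3 adjusted over the list alone, camera adjusted p = 9.6e-07, adjusted p = 0.311 with an estimated correlation). The auxin-conjugating GH3.3 (AT2G23170, 1.09 ± 0.26) and the alternative oxidase AOX1A (AT3G22370, 0.80 ± 0.18) rose. Chalcone synthase, TT4 (AT5G13930), differed by 0.08 ± 0.54 (adjusted p = 0.999) and the sulfate-reducing APR1 (AT4G04610) by 0.44 ± 0.21 (adjusted p = 0.416). In all, 311 genes rose and 603 fell. The count was 608 without EtOH replicate 2 and 522 without t-chalcone replicate 2, and edgeR called 1151 higher and 1638 lower, all 914 among them.

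In roots at 3 h, the sugar-starvation marker DIN2 (AT3G60140) showed a change of 3.98 ± 0.28, from 104 ± 30.2 to 1620 ± 341 (adjusted p = 2.39e-11). Other increases among genes with a symbol were in HSP17.4 (3.31 ± 0.44), BGLU28 (3.26 ± 0.87), the cytochrome P450 CYP72A8 (AT3G14620, 3.15 ± 0.32), LSU1 (48.1 ± 11.3 to 407 ± 8.66, 3.08 ± 0.28, adjusted p = 2.81e-09) and UGT75B1 (2.85 ± 0.34). The ferric reductase FRO2 (AT1G01580) fell from 1260 ± 353 to 132 ± 25.7 (-3.23 ± 0.41, adjusted p = 2.28e-06). The cytochrome P450 gene CYP82C4 (AT4G31940) fell by 2.84 ± 0.48 and the iron transporter IRT1 (AT4G19690) by 2.38 ± 0.38. The glutathione transferase GSTF14 (AT1G49860, -2.83 ± 0.21, adjusted p = 1.06e-10), the terpene synthase TPS-CIN (AT3G25830, -2.83 ± 0.92), XTH13 (AT5G57540, -2.68 ± 0.41) and XTH12 (-2.60 ± 0.41) fell too.

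Detoxification genes rose in 18 of 24 cases and 6 did not pass (19 adjusted over the list alone, camera adjusted p = 1.11e-17), and GSTU24 (2.30 ± 0.23), CYP81D8 (2.52 ± 0.28) and UGT74E2 (1.88 ± 0.24) stayed higher. Of 11 glucosinolate genes, 8 fell and 3 did not pass (10 adjusted over the list alone, camera adjusted p = 1.11e-17), including the chain-elongation enzyme BCAT4 (AT3G19710, -1.64 ± 0.18) and the cytochromes CYP79F2 (AT1G16400, -1.59 ± 0.20) and CYP83A1 (AT4G13770, -1.57 ± 0.17). Both lists passed with an estimated correlation. Of 24 heat shock genes, 16 rose, with AT1G53540 at 4.36 ± 0.61 and AT2G29500 at 3.39 ± 0.23, and 8 did not pass (20 adjusted over the list alone, camera adjusted p = 1.71e-10, adjusted p = 0.0936 with an estimated correlation). Of 23 proteasome genes, 20 rose and 3 did not pass (21 adjusted over the list alone, camera adjusted p = 9.44e-10, adjusted p = 0.282 with an estimated correlation). Among them were NAC053 (AT3G10500), a transcription factor of proteasome stress (1.28 ± 0.16), and the subunits RPN10 (AT4G38630, 1.03 ± 0.27) and PBE1 (AT1G13060, 0.75 ± 0.26). Without the libraries under 0.5 M, 8 proteasome genes passed, edgeR on all libraries passed 9, RPN10 stood at 0.49 and PBE1 lost its call.

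Sulfur assimilation rose in 11 of 20 genes, including ATSDI1 (AT5G48850, 2.77 ± 0.48), with 9 not past the test (12 adjusted over the list alone, camera adjusted p = 2.23e-08, adjusted p = 0.124 with an estimated correlation). Abscisic acid genes rose in 11 of 18 cases, including CYP707A1 (AT4G19230, 1.77 ± 0.44) and HAI1 (AT5G59220, 1.72 ± 0.31), with 7 not past it (13 adjusted over the list alone, camera adjusted p = 2.08e-06, adjusted p = 0.0936 with an estimated correlation). Starvation genes rose in 7 of 13 cases, with the asparagine synthetase ASN1 (AT3G47340) at 1.82 ± 0.36 (7 adjusted over the list alone, camera adjusted p = 0.00347, adjusted p = 0.282 with an estimated correlation). Redox genes rose in 9 of 24 cases, with the zinc finger RHL41 (AT5G59820) at 1.60 ± 0.32 (12 adjusted over the list alone, camera adjusted p = 0.00273, adjusted p = 0.375 with an estimated correlation). Of 8 cytokinin genes, the response regulators ARR15 (AT1G74890, -1.83 ± 0.61) and ARR7 (AT1G19050, -1.26 ± 0.33) fell and 6 did not pass (2 adjusted over the list alone, camera adjusted p = 0.00127, adjusted p = 0.177 with an estimated correlation). Of 22 cell cycle genes, 2 fell, namely CYCA1;1 (AT1G44110, -0.90 ± 0.19) and MCM3 (AT5G46280, -0.50 ± 0.17) (1 adjusted over the list alone, camera adjusted p = 0.000208, adjusted p = 0.375 with an estimated correlation). Circadian clock genes moved both ways. ELF4 (AT2G40080, 1.81 ± 0.28), FKF1 (AT1G68050, 1.45 ± 0.34) and TOC1 (AT5G61380, 575 ± 131 to 1250 ± 62.0) were among 5 of 14 that rose, and LHY (AT1G01060, -1.08 ± 0.33) was the 1 that fell (6 adjusted over the list alone, camera adjusted p = 0.0549). The camera p of this list passed under TMM scaling, at 0.0131 (adjusted p = 0.451 with an estimated correlation and the deposited scaling).

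Of 16 iron genes, 4 fell, 3 rose, among them the regulator bHLH39 (AT3G56980, 1.1 ± 0.31), and 9 did not pass (9 adjusted over the list alone, camera adjusted p = 0.0414 with the list lower, adjusted p = 0.572 with an estimated correlation, and 0.185 under TMM scaling). In all, 2042 genes rose and 646 fell. The control EtOH replicate 1 held 0.128 M. Without the libraries under 0.5 M 1054 genes rose and 592 fell, 1317 of them called with all libraries too, with TPS-CIN (adjusted p = 0.224), MCM3 (0.0648) and bHLH39 (0.0781) losing their calls and ARR15 no longer tested. The medians of redox and cytokinin genes were then 0.23 and -0.41 against 0.36 and -0.66. With array weights 445 genes passed, and 384 with only the groups of the contrast in the fit. Leaving out EtOH replicate 1 or 3 gave 1028 and 5427 genes, and leaving out t-chalcone replicate 1, 2 or 3 gave 1457, 1368 and 1349.

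In roots at 6 h, the kinase gene MPK11 (AT1G01560) rose by 2.37 ± 0.48. The cytochrome P450 CYP81F2 (AT5G57220) and the methyltransferase IGMT2 (AT1G21120), which modify indole glucosinolates, rose by 2.19 ± 0.32 (257 ± 147 to 1030 ± 118, adjusted p = 0.000584) and 2.17 ± 0.38. CYP71A12 (AT2G30750), of the camalexin pathway, rose by 2.02 ± 0.38 (adjusted p = 0.00547). The methyltransferase PXMT1 (AT1G66700, 1.99 ± 0.33) and the transcription factor NAC042 (AT2G43000, 1.98 ± 0.31) rose with them. GSTF14 fell again (759 ± 107 to 215 ± 48.5, -1.83 ± 0.21, adjusted p = 1.63e-05). Decreases were also found in the clock genes PRR7 (AT5G02810, -1.61 ± 0.27) and EPR1 (AT1G18330, -1.55 ± 0.27) and the lipid transfer protein gene AZI1 (AT4G12470, -1.39 ± 0.28). GSTU24 was at 0.65 ± 0.23 (adjusted p = 0.462), short of the threshold.

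Of 12 camalexin genes at 6 h, 3 rose, CYP71A12 together with the transcription factors MYB51 (AT1G18570, 1.46 ± 0.28) and WRKY33 (AT2G38470, 1.28 ± 0.24), and 9 did not pass (4 adjusted over the list alone, camera adjusted p = 1.7e-09). Of 14 salicylic acid genes, CBP60G (AT5G26920, 1.88 ± 0.39) and WRKY70 (AT3G56400, 1.68 ± 0.29) rose and 12 did not pass (4 adjusted over the list alone, camera adjusted p = 8.44e-08). Detoxification genes rose in 3 of 24 cases, with CYP81D8 at 1.24 ± 0.28 and the oxophytodienoate reductase OPR1 (AT1G76680) at 1.02 ± 0.16 (10 adjusted over the list alone, camera adjusted p = 4.12e-18). All 3 lists passed with an estimated correlation. Sulfur assimilation rose in 2 of 20 genes (5 adjusted over the list alone, camera adjusted p = 8.44e-08, adjusted p = 0.151 with an estimated correlation). Glutathione transferases had 2 of 39 higher, with GSTU4 (AT2G29460) at 1.75 ± 0.21, 1 lower and 36 not past the test (10 adjusted over the list alone, camera adjusted p = 3.91e-05, adjusted p = 0.343 with an estimated correlation). Of 13 flavonoid genes limma called 0 over all genes, with 8 at an unadjusted p under 0.05, 0 by edgeR and 6 adjusted over the list alone. Their median was 0.90 (camera adjusted p = 1.03e-06, adjusted p = 0.139 with an estimated correlation). Glucosinolate genes were lower as a list (11 genes, median -0.29, camera adjusted p = 0.000105, adjusted p = 0.383 with an estimated correlation). Limma called 0 of them, with 3 at an unadjusted p under 0.05, 0 adjusted over the list alone and 0 by edgeR. Photosynthesis genes (38 genes, median -0.47) and clock genes (14 genes, median -0.12) were lower too, with camera adjusted p-values of 2.66e-08 and 0.0279, and adjusted p = 0.479 and adjusted p = 0.466 with an estimated correlation. Of these, limma called 0 photosynthesis genes (6 at an unadjusted p under 0.05, 1 by edgeR, 1 adjusted over the list alone) and 1 clock gene (8 adjusted over the list alone). In all, 75 genes rose and 14 fell. The count was 13 without EtOH replicate 1, and 47 and 30 without t-chalcone replicates 1 and 3, and edgeR called 201 higher and 68 lower, 87 of the 89 among them.

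At 12 h in roots, 6 genes passed. The mitochondrial AAA-type ATPase gene AATP1 (AT5G40010) rose from 85.5 ± 14.5 to 267 ± 102 (1.58 ± 0.22, adjusted p = 0.00132). The protein kinase gene SNRK2.9 (AT2G23030) rose by 1.07 ± 0.21 (adjusted p = 0.0447) and PDC2 (AT5G54960), a pyruvate decarboxylase of fermentation, by 0.84 ± 0.16 (adjusted p = 0.0356). The others, AT1G13480 (1.27 ± 0.24), AT1G28600 (0.95 ± 0.18) and AT5G38100 (-1.31 ± 0.19), have no symbol and were named after their values were seen. GSTU24 differed by 0.50 ± 0.23 (adjusted p = 0.615). By camera, glutathione transferases (median 0.11, adjusted p = 5.98e-05), salicylic acid (0.43, 0.000404) and detoxification genes (0.16, 0.00617) were higher as lists, and auxin transport (-0.26, 0.00527) and glucosinolate genes (-0.24, 0.0256, and 0.0847 under TMM scaling) lower. With an estimated correlation these gave adjusted p = 0.662, 0.662, 0.742, 0.662 and 0.847. Limma called 0 of their 39, 14, 24, 12 and 11 genes, with 10, 4, 4, 4 and 4 at an unadjusted p under 0.05, 8, 2, 0, 0 and 1 adjusted over the list alone, and by edgeR 6 higher and 1 lower, 1 higher, 0, 0 and 1 lower. Over all genes 1525 had an unadjusted p under 0.05, and edgeR called 171 higher and 166 lower, all 6 among them. The count was 2 without EtOH replicate 1 or 2 and 32 without t-chalcone replicate 2. With only the groups of the contrast in the fit limma called 0, and DESeq2 called 86.

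Roots at 24 h had 12 genes higher and 366 lower. The clock gene PRR5 (AT5G24470, 52.6 ± 9.17 to 129 ± 8.14, 1.29 ± 0.25, adjusted p = 0.00801) and PDC2 (1.19 ± 0.16, adjusted p = 0.000149) rose. The triterpene synthase gene THAS1 (AT5G48010, 508 ± 173 to 1070 ± 14), the cation exchanger gene CHX16 (AT1G64170, 1.08 ± 0.22) and the abscisic acid response factor ABF1 (AT1G49720, 0.84 ± 0.21) rose too. The ubiquitin ligase gene ARI12 (AT1G05880) fell from 163 ± 21.4 to 30.1 ± 20.8 (-2.78 ± 0.46, adjusted p = 0.00191). MPK11 (-2.41 ± 0.48), the transcription factor MYB122 (AT1G74080, -1.94 ± 0.41), the ubiquitin ligase gene PUB54 (AT1G01680, -1.80 ± 0.47), the glutathione transferase GSTU12 (AT1G69920, -1.76 ± 0.29) and the blue copper protein gene BCB (AT5G20230, -1.73 ± 0.37) fell too. Of 39 glutathione transferases, 6 fell, with GSTU4 at -1.62 ± 0.21 and GSTF6 (AT1G02930) at -1.13 ± 0.22, and 33 did not pass (8 adjusted over the list alone, camera adjusted p = 0.0742, and 0.0202 under TMM scaling, adjusted p = 0.748 with an estimated correlation and the deposited scaling). Of 14 salicylic acid genes, WRKY70 fell (-1.12 ± 0.29) and 13 did not pass (8 adjusted over the list alone, median -0.73, camera adjusted p = 0.000866, adjusted p = 0.748 with an estimated correlation). Sulfur assimilation (20 genes), iron (16), flavonoid (13) and root hair lists (10) were higher by camera (medians 0.22, 0.21, 0.15 and 0.11, adjusted p = 0.000313, 0.00962, 0.0156 and 0.019, each adjusted p = 0.748 with an estimated correlation). Under TMM scaling iron and root hair genes had 0.114 and 0.123, and flavonoid genes 0.0604 without the libraries under 0.5 M. Limma called 0 of these genes, with 3, 3, 2 and 1 at an unadjusted p under 0.05, 0 adjusted over the list alone and 1 flavonoid gene by edgeR. Of 14 clock genes, 4 fell, including RVE1 (AT5G17300, -1.23 ± 0.23), LHY (-1.23 ± 0.33) and CCA1 (AT2G46830, -1.13 ± 0.30), 2 rose, PRR5 and FKF1 (1.49 ± 0.34), and 8 did not pass (9 adjusted over the list alone). Camera set this list higher (adjusted p = 0.282), at a median of -0.02 and a mean of -0.07. GH3.3 fell by 0.96 ± 0.26. All 3 t-chalcone libraries at this time carried S numbers in their descriptions and held 0.866 to 2.19 M, against 9.30 to 14.3 M in controls with index sequences. With a term for the S number 0 genes passed in limma, and 749 had an unadjusted p under 0.05 against 3452 without the term. EdgeR without the term called 37 higher and 324 lower, with 237 of the 378 limma calls among them. TMM scaling left 11 higher and 195 lower, and leaving out EtOH replicates 1, 2 or 3 gave 120, 158 and 31 genes and t-chalcone replicates 1 or 2 gave 182 and 210.

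In shoots at 1 h, 11 genes passed. The glutathione transferase GSTU25 (AT1G17180) rose from 5.07 ± 2.16 to 67.7 ± 28.5 (3.46 ± 0.43, adjusted p = 0.000228). The cytochrome P450 CYP81D11 (AT3G28740) rose from 32.3 ± 1.63 to 186 ± 70.5 (2.42 ± 0.40, adjusted p = 0.012) and the glycosyltransferase UGT73B3 (AT4G34131) by 1.77 ± 0.33. The small heat shock gene AT2G29500 (1.89 ± 0.37) and the auxin-responsive SAUR19 (AT5G18010, 2.13 ± 0.42) rose as well. The cell death regulator gene BAP1 (AT3G61190) fell from 283 ± 215 to 37.9 ± 17.3 (-2.59 ± 0.50, adjusted p = 0.0426), together with CML23 (AT1G66400), a calmodulin-like gene (-2.23 ± 0.43), and the alcohol dehydrogenase gene ADH1 (AT1G77120, -2.02 ± 0.39). The remaining calls, AT3G13310 (2.15 ± 0.37), AT1G26390 (-3.40 ± 0.56) and AT5G17350 (-3.14 ± 0.54), have no symbol and were named after their values were seen. GSTU24 was at 2.27 ± 0.46 (adjusted p = 0.0635) and HSP70 at 2.17 ± 0.45 (adjusted p = 0.0685), short of the threshold.

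Heat shock genes were higher as a list in shoots at 1 h (median 0.65, camera adjusted p = 9.71e-17), with 1 of 26 called and 8 adjusted over the list alone. Auxin genes were higher too (median 0.27, camera adjusted p = 5.01e-12), with 1 of 33 called and 7 adjusted over the list alone. Lists of jasmonate (23 genes, median -0.68, camera adjusted p = 1.14e-12), salicylic acid (18 genes, median -0.70, 1.02e-10), camalexin (12 genes, median -0.72, 2.86e-08) and ethylene genes (17 genes, median -0.36, 8.41e-08) were lower. No member of these 4 passed in limma over all genes, with 5, 1, 1 and 3 at an unadjusted p under 0.05, 2, 0, 1 and 1 called lower by edgeR, and 0, 1, 1 and 1 adjusted over the list alone. All 6 lists passed with an estimated correlation. Detoxification genes had 2 of 27 higher (6 adjusted over the list alone, camera adjusted p = 5.99e-07, adjusted p = 0.131 with an estimated correlation). Glutathione transferases had 1 of 40 higher (7 adjusted over the list alone, camera adjusted p = 0.000212, adjusted p = 0.0855 with an estimated correlation), at a median of -0.04 and a mean of 0.25. Clock genes were higher as a list (14 genes, median 0.14, camera adjusted p = 0.0057, adjusted p = 0.0481 with an estimated correlation), but not without the libraries under 0.5 M (adjusted p = 0.129). Limma called 0 of them, with 2 at an unadjusted p under 0.05, 1 adjusted over the list alone and 1 lower by edgeR. Photosynthesis genes were at a median of 0.09 (camera adjusted p = 0.000998, adjusted p = 0.379 with an estimated correlation, and 0.0535 without those libraries). In all, 6 genes rose and 5 fell, against 10 and 5 with median-of-ratios scaling within shoots and 44 and 137 with edgeR, all 11 among them. Leaving out EtOH replicates 1, 2 or 3 gave 2, 1 and 58 genes, and leaving out t-chalcone replicates 1, 2 or 3 gave 1, 3 and 7. A term for the S number and leaving out the S-number libraries each gave 5.

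At 3 h in shoots, 7 genes rose and 1 fell. The glutathione transferases GSTU1 (AT2G29490, 107 ± 28.4 to 395 ± 50.4, 1.9 ± 0.33, adjusted p = 0.0121) and GSTU19 (AT1G78380, 2890 ± 279 to 6830 ± 330, 1.24 ± 0.18, adjusted p = 0.00225) rose. So did the B-box protein gene BBX8 (AT5G48250, 1.38 ± 0.24), DJ1A (AT3G14990), a gene for a protein of oxidative stress (1.12 ± 0.17), and AT2G29500 (2.46 ± 0.37). AT3G13310 (2.27 ± 0.37), AT3G59930 (3.89 ± 0.69) and the decrease, AT5G59680 (-2.36 ± 0.38), have no symbol and were named after their values were seen. GSTU24 was at 1.60 ± 0.46 (adjusted p = 0.314).

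Several gene lists passed in shoots at 3 h. Detoxification genes had a median of 1.1 (camera adjusted p = 5.19e-22) with 0 of 27 called by limma over all genes, 13 at an unadjusted p under 0.05, 10 adjusted over the list alone and 10 by edgeR. Photosynthesis genes had a median of -0.49 (camera adjusted p = 3.04e-34) with 0 of 38 called by limma, 26 at an unadjusted p under 0.05, 22 adjusted over the list alone and 2 by edgeR. Glutathione transferases (2 of 40 higher, 6 adjusted over the list alone, camera adjusted p = 3.34e-10) and heat shock genes (1 of 26, 2 adjusted over the list alone, 1.19e-10) were higher. The jasmonate list was higher as well (median 0.66, camera adjusted p = 1.53e-11), with 0 of 23 called by limma, 5 at an unadjusted p under 0.05, 3 adjusted over the list alone and 3 by edgeR. The chlorophyll list was lower (median -0.36, camera adjusted p = 2.32e-06), with 0 of 12 called by limma, 5 at an unadjusted p under 0.05, 0 adjusted over the list alone and 0 by edgeR. Sulfur assimilation (20 genes, median 0.29, camera adjusted p = 2.32e-06), abscisic acid (22 genes, median 0.30, 0.00023) and iron genes (16 genes, median 0.38, 3e-06) were higher. Limma called 0 members of these, with 4, 3 and 7 at an unadjusted p under 0.05, 4, 1 and 6 adjusted over the list alone and 2, 1 and 5 by edgeR. All 9 lists passed with an estimated correlation, and the median of iron genes was 0.17 without the libraries under 0.5 M. Without these libraries, none of which belongs to this time, 311 genes rose and 996 fell, and edgeR with all libraries called 260 and 34, all 8 among them in both. Leaving out EtOH replicates 1 or 2 gave 5 and 4 genes, and leaving out t-chalcone replicates 2 or 3 gave 80 and 3.

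In shoots at 6 h, genes for light-harvesting proteins were among the largest decreases. CAB2 (AT1G29920) fell from 11700 ± 1240 to 191 ± 46.2 (-5.95 ± 0.25, adjusted p = 2.36e-16). LHCB2.2 (AT2G05070) fell from 8540 ± 644 to 169 ± 4.34 (-5.65 ± 0.17, adjusted p = 5.03e-20) and LHCB2.1 (AT2G05100) from 11000 ± 1320 to 310 ± 29.2 (-5.14 ± 0.15, adjusted p = 5.03e-20). The protein kinase gene CIPK20 (AT5G45820, -5.66 ± 0.32), PORA (AT5G54190), a protochlorophyllide reductase gene (-5.60 ± 0.47), and the clock gene PRR9 (AT2G46790, 52.3 ± 3.24 to 1.05 ± 0.357, -4.71 ± 0.40, adjusted p = 2.41e-09) fell with them. The MYB-like gene RVE2 (AT5G37260) rose from 168 ± 62.9 to 1890 ± 225 (3.54 ± 0.55, adjusted p = 0.000196). Increases were also found in cPT4 (AT5G58770, 2.40 ± 0.51), the iron regulator BHLH100 (AT2G41240, 2.35 ± 0.51), the cellulose synthase-like CSLB03 (AT2G32530, 2.26 ± 0.48), the wall acetylation family member TBL26 (AT4G01080, 2.22 ± 0.45) and the hydroperoxide lyase gene HPL1 (AT4G15440, 2.2 ± 0.40).

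Of 38 photosynthesis genes in shoots at 6 h, 22 fell, 4 rose, with the Rubisco small subunit gene RBCS1B (AT5G38430) at 1.72 ± 0.32, and 12 did not pass (33 adjusted over the list alone, camera adjusted p = 3.12e-43). Of 12 chlorophyll genes, 6 fell and 6 did not pass (6 adjusted over the list alone, camera adjusted p = 1.39e-16), including PORB (AT4G27440, -2.05 ± 0.38) and CH1 (AT1G44446, -1.60 ± 0.17). Of 14 clock genes, 5 fell and 9 did not pass (7 adjusted over the list alone, camera adjusted p = 8.08e-17), with PRR7 at -3.37 ± 0.24 and GI (AT1G22770) at -2.80 ± 0.23. Of 33 auxin genes, 8 fell and 25 did not pass (14 adjusted over the list alone, camera adjusted p = 3.33e-18), with IAA29 (AT4G32280) at -3.08 ± 0.46 and ACS4 (AT2G22810) at -2.78 ± 0.72. Sulfur assimilation rose in 2 of 20 genes (4 adjusted over the list alone, camera adjusted p = 6.19e-06). These 5 lists passed with an estimated correlation. Iron genes rose in 4 of 16 cases, with bHLH38 (AT3G56970) at 1.98 ± 0.47 (5 adjusted over the list alone, camera adjusted p = 2.78e-06, adjusted p = 0.0534 with an estimated correlation). Of 12 endoplasmic reticulum stress genes, the chaperone gene BIP1 (AT5G28540) rose (0.90 ± 0.18) and 11 did not pass (3 adjusted over the list alone, camera adjusted p = 0.000178, adjusted p = 0.0634 with an estimated correlation). Of 6 nucleolus genes, NOP56 (AT1G56110) rose (0.84 ± 0.22) and 5 did not pass (1 adjusted over the list alone, camera adjusted p = 0.00318, adjusted p = 0.0586 with an estimated correlation). The jasmonate synthesis gene LOX2 (AT3G45140) rose (1.81 ± 0.32), while the flavonoid repressor gene MYBL2 (AT1G71030, -2.37 ± 0.23) and ASN1 (-2.22 ± 0.31) fell.

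In all, 153 genes rose and 202 fell in shoots at 6 h. Without the libraries under 0.5 M, none of which belongs to this time, 2952 rose and 1478 fell, and edgeR with all libraries called 1589 and 1167, all 355 among them in both. Leaving out EtOH replicates 1 or 3 gave 181 and 193 genes, and leaving out t-chalcone replicates 1, 2 or 3 gave 185, 168 and 233.

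At 12 h in shoots, the sulfate-reducing APR3 rose from 215 ± 128 to 1800 ± 709 (3.22 ± 0.43, adjusted p = 0.000206) and APR1 from 213 ± 135 to 803 ± 256 (2.1 ± 0.41, adjusted p = 0.00798). AOC2 (AT3G25770), of jasmonate synthesis, rose from 63.0 ± 26.9 to 329 ± 43.3 (2.44 ± 0.26, adjusted p = 3.44e-06). The glycosyltransferase UGT73B5 (AT2G15480, 2.35 ± 0.41), OPR1 (2.33 ± 0.39), GSTU1 (2.27 ± 0.33), the aldolase gene FBA5 (AT4G26530, 2.87 ± 0.59) and the resistance gene RPP4 (AT4G16860, 2.47 ± 0.44) rose too. BT2 (AT3G48360), a BTB protein gene, fell from 4890 ± 1700 to 1010 ± 401 (-2.27 ± 0.32, adjusted p = 0.000334). So did the stress gene OXS3 (AT5G56550, -1.79 ± 0.37), DIM1A (AT2G47420, -1.69 ± 0.40), the homeobox gene HB-12 (AT3G61890, -1.64 ± 0.39), BT5 (AT4G37610, -1.60 ± 0.34) and RVE1 (-1.52 ± 0.30). Without EtOH replicate 2, which held 0.246 M, and the other libraries under 0.5 M, these values were 2.63 for APR3, 1.56 for FBA5, 1.44 for RPP4, -0.882 for DIM1A and -0.811 for HB-12, all still past the threshold.

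Of 27 detoxification genes, 6 rose and 21 did not pass (14 adjusted over the list alone, camera adjusted p = 4.24e-05). Of 20 sulfur assimilation genes, 3 rose and 17 did not pass (9 adjusted over the list alone, camera adjusted p = 0.000197). Of 40 glutathione transferases, 3 rose and 37 did not pass (13 adjusted over the list alone, camera adjusted p = 0.00357). With an estimated correlation these 3 lists gave adjusted p = 0.716, adjusted p = 0.454 and adjusted p = 0.716. Glucosinolate genes had a median of 1.67 with SOT17 (AT1G18590, 1.72 ± 0.38) called of 13 (11 adjusted over the list alone, camera adjusted p = 4.24e-05, adjusted p = 0.716 with an estimated correlation). Photosynthesis genes rose in 4 of 38 cases, including PSAO (AT1G08380, 1.02 ± 0.23) (12 adjusted over the list alone, camera adjusted p = 0.00217, adjusted p = 0.791 with an estimated correlation). Of 23 jasmonate genes, AOC2, LOX2 (1.68 ± 0.32) and AOC1 (AT3G25760, 1.47 ± 0.31) rose and 20 did not pass (7 adjusted over the list alone, camera adjusted p = 0.331). Of 14 clock genes, PRR9 (1.93 ± 0.40) and GI (1.2 ± 0.23) rose, RVE1 fell and 11 did not pass (4 adjusted over the list alone, camera adjusted p = 0.901). Without the libraries under 0.5 M the medians of glucosinolate and detoxification genes were 0.36 and 0.70, against 1.67 and 1.13 with them. SOT17 and PSAO then stood at 0.98 and 0.52, both still past the threshold. In all, 118 genes rose and 56 fell, and without the libraries under 0.5 M 377 rose and 453 fell, 163 of the 174 among them. Leaving out EtOH replicates 1, 2 or 3 gave 8876, 294 and 8935 genes, and leaving out t-chalcone replicates 1, 2 or 3 gave 22, 68 and 104. With only the groups of the contrast in the fit limma called 0 genes, against 6853 at an unadjusted p under 0.05 with all groups, 555 by edgeR and 1254 by DESeq2.

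Shoots at 24 h had lower levels of DFR, LDOX and TT4, genes of flavonoid synthesis. Dihydroflavonol reductase, DFR (AT5G42800), fell from 190 ± 90.0 to 9.84 ± 7.12 (-4.28 ± 0.57, adjusted p = 0.000125). Anthocyanidin synthase, LDOX (AT4G22880), fell from 176 ± 67.0 to 10.5 ± 7.07 (-4.11 ± 0.70, adjusted p = 0.00159) and chalcone synthase, TT4, from 676 ± 137 to 71.4 ± 28.6 (-3.27 ± 0.71, adjusted p = 0.0183). The sugar transporter gene SAG29 (AT5G13170, -3.51 ± 0.53), the light stress gene ELIP2 (AT4G14690, -3.42 ± 0.79) and GSTF12 (AT5G17220), a glutathione transferase of anthocyanin transport (-3.17 ± 0.58), fell with them. In t-chalcone replicates 1 and 2, DFR, LDOX and GSTF12 stood at the library's lowest value, so their levels there are upper limits. The cold-regulated COR413IM1 (AT1G29395) rose from 22.5 ± 1.31 to 175 ± 26.5 (2.90 ± 0.35, adjusted p = 4.95e-05). Other increases were in BCAT-2 (AT1G10070), of branched-chain amino acid metabolism (2.81 ± 0.70), the senescence gene SEN1 (AT4G35770, 2.24 ± 0.53), CCL (AT3G26740, 1.98 ± 0.30), GRF11 (AT1G34760, 1.96 ± 0.49, and 1.07 without the libraries under 0.5 M) and XTH25 (AT5G57550, 1.91 ± 0.35).

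Of 20 flavonoid genes, 8 fell and 12 did not pass (12 adjusted over the list alone, median -1.26, camera adjusted p = 1.46e-13, adjusted p = 0.135 with an estimated correlation). Their median was -2.28 without the libraries under 0.5 M. Of 19 phenylpropanoid genes, 4CL3 (AT1G65060) fell (-2.07 ± 0.40) and 18 did not pass (9 adjusted over the list alone, camera adjusted p = 2.82e-07, adjusted p = 0.287 with an estimated correlation). Of 13 glucosinolate genes, SOT17 fell (-1.52 ± 0.38) and 12 did not pass (4 adjusted over the list alone, camera adjusted p = 2.82e-07, adjusted p = 0.339 with an estimated correlation). APR1 fell (-1.87 ± 0.41) as 1 of 20 sulfur assimilation genes (8 adjusted over the list alone, camera adjusted p = 0.00724, adjusted p = 0.339 with an estimated correlation). HSP70 fell (-2.32 ± 0.45) as 1 of 26 heat shock genes (2 adjusted over the list alone, camera adjusted p = 0.00148, adjusted p = 0.394 with an estimated correlation). Of 40 glutathione transferases, 3 fell, including ERD9 (AT1G10370, -2.55 ± 0.62) and GSTU20 (AT1G78370, -1.43 ± 0.27) (4 adjusted over the list alone, camera adjusted p = 0.101). Of 38 photosynthesis genes, 4 fell, including RBCS1B (-1.45 ± 0.32) and FBA1 (AT2G21330, -1.18 ± 0.22), at a list median of 0.05 and a mean of -0.14 (9 adjusted over the list alone, camera adjusted p = 0.113). Of 22 abscisic acid genes, 3 rose, including RAB18 (AT5G66400, 1.86 ± 0.36, adjusted p = 0.0904 by edgeR), and 19 did not pass, at a median of -0.01 and a mean of 0.03 (6 adjusted over the list alone, camera adjusted p = 0.305). In all, 122 genes rose and 140 fell, against 163 and 117 with TMM scaling, and 1162 and 1276 without the libraries under 0.5 M, of which EtOH replicate 3 and t-chalcone replicate 2 belong to this time. Leaving out EtOH replicates 1, 2 or 3 gave 513, 124 and 139 genes, and leaving out t-chalcone replicate 1 gave 94. Array weights gave 0 genes in limma, against 2442 at an unadjusted p under 0.05 without weights, 533 by edgeR and 580 by DESeq2. The edgeR calls held 202 of the 262 limma calls. Leaving out the S-number libraries gave 55, and another split of the same 6 libraries gave 273 against the real 262.

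**Figure D3:**
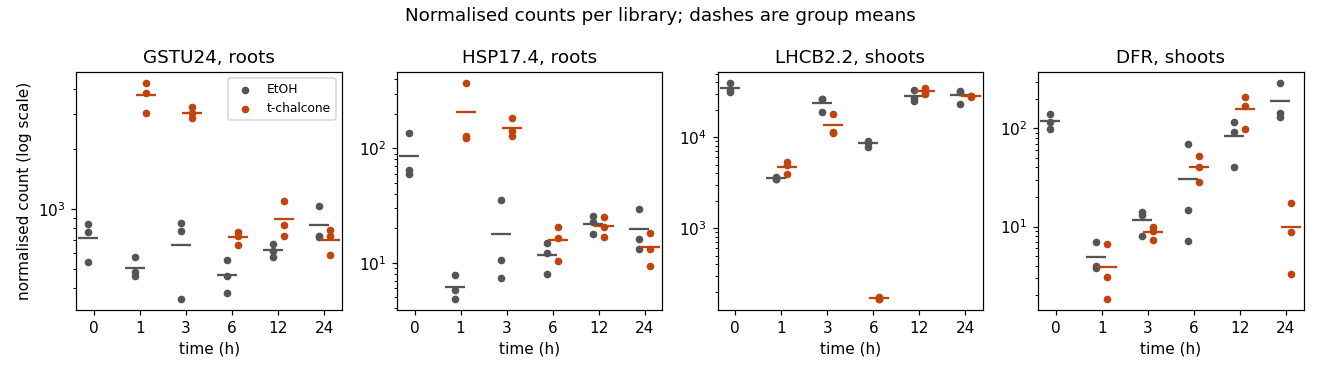
Deposited values of GSTU24 and HSP17.4 in roots and of LHCB2.2 and DFR in shoots for every library at each time (x axis, h; y axis logarithmic), with dashes at the group means. GSTU24 lies at 3720 against 507 at 1 h, LHCB2.2 at 169 against 8540 at 6 h and DFR at 9.84 against 190 at 24 h (t-chalcone against EtOH means).

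**Figure D4:**
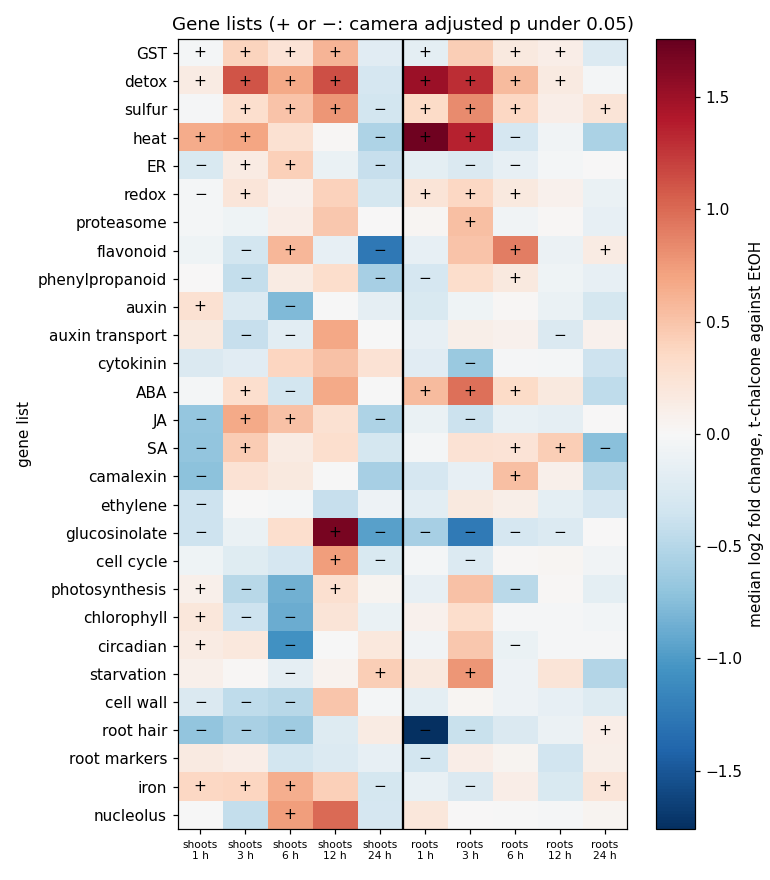
Median log2 fold change of each gene list (rows) in each comparison (columns, tissue and time in h), with + or - where camera's adjusted p was under 0.05 for a higher or lower list. Detoxification genes stand at 1.5 in roots at 1 h and 1.3 at 3 h, photosynthesis genes at -0.84 in shoots at 6 h and flavonoid genes at -1.26 in shoots at 24 h.

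Across the 28 lists and 5 times, camera passed 67 list tests in shoots, 33 higher and 34 lower, and 48 in roots, 29 higher and 19 lower. With an estimated correlation 21 passed in shoots and 9 in roots, all of them named for their comparison. Other splits of the libraries gave a median of 36 passes in shoots and 30 in roots at the preset correlation. The 10 comparisons share no libraries, and 50 overlaps of their calls were computed with two-sided Fisher exact tests. Of genes higher in roots at 1 h, 240 were also higher at 3 h against 32.0 for independent lists (adjusted p = 1.06e-173), and 224 were lower at both times against 19.6 (adjusted p = 4.58e-183). Roots at 3 h and 6 h shared 52 higher genes against 7.72 (adjusted p = 4.57e-33). Shoots and roots at 1 h shared 4 higher genes, AT2G29500, CYP81D11, GSTU25 and UGT73B3, against 0.0784 (adjusted p = 2.09e-06). At 3 h they shared 5 higher genes (adjusted p = 0.000919) and at 6 h 4 lower ones (2.73e-05), and the 7 other overlaps of tissues, of 0 to 4 genes, did not pass. The genes of 1 h were named after their values were seen, and 1 was left without shoots EtOH replicate 1 or 2 or t-chalcone replicate 1 or 2, and 2 without shoots EtOH replicate 3. The genes lower in roots at both 1 h and 3 h numbered 129 without t-chalcone replicate 2 of 1 h and 145 without t-chalcone replicate 1 of 3 h. Genes higher at both 3 h and 6 h numbered 9, 25 and 19 without EtOH replicate 1 or t-chalcone replicates 1 or 3 of 6 h.

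Differences in the effect of t-chalcone between shoots and roots were tested next. They passed for 27 genes at 1 h, 15 at 3 h, 46 at 6 h, 34 at 12 h and 300 at 24 h. At 1 h the effect on FRO4 was -2.79 in roots and -0.20 in shoots, a difference of 2.59 ± 0.55 (adjusted p = 0.0279). At 6 h the effect on LHCB2.2 in shoots minus that in roots was -5.97 ± 0.74 (adjusted p = 1.22e-06), and at 24 h that on DFR was -6.75 ± 1.02 (adjusted p = 0.000126). For the latter, the effect in shoots was -4.28 and that in roots 2.47 (0.97 ± 0.646 to 12.6 ± 9.69 in roots, where DFR did not pass, adjusted p = 0.125). Root EtOH replicates 2 and 3 and t-chalcone replicate 3 stood at the library's lowest value for DFR. At 24 h a term for the S number, which the t-chalcone root libraries carried, took the 300 to 32. Array weights took it to 0 in limma, against 2858 genes at an unadjusted p under 0.05 without weights.

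Leaving out any 1 h library but shoots t-chalcone replicate 2 took the tissue count at 1 h to between 10 and 16, or to 43 without roots t-chalcone replicate 3 and 101 without shoots EtOH replicate 3. At 3 h, leaving out any library took it to between 0 and 2, or to 38 and 760 without roots EtOH replicates 2 and 3 and 195 without shoots t-chalcone replicate 2. These counts are by limma, the tool run for tissues, and 3728 genes at 3 h had an unadjusted p under 0.05 with all libraries. At 6 h, leaving out roots EtOH replicate 2 or 3, roots t-chalcone replicate 1 or 2, shoots EtOH replicate 3 or shoots t-chalcone replicate 2 gave 24 to 30. At 12 h, leaving out roots EtOH replicates 2 or 3 gave 11 and 7, roots t-chalcone replicates 1 or 3 gave 74 and 21, shoots EtOH replicates 1 or 3 gave 7283 and 7317 and shoots t-chalcone replicate 1 gave 5. At 24 h, leaving out roots EtOH replicates 1 or 3 gave 180 and 95, roots t-chalcone replicates 1 or 2 gave 171 and 180, shoots EtOH replicates 1 or 3 gave 843 and 111. Shoots t-chalcone replicates 1, 2 or 3 of that time gave 183, 451 and 183.

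Between times, the effect differed for 614 genes in shoots and 1628 in roots by a limma F test. Among clock genes in shoots, the effect on PRR7 was -3.37 at 6 h and 1.27 at 24 h. Without 6 h EtOH replicates 1 or 3 the shoot count was 401 and 392, without 6 h t-chalcone replicates 1 or 2 it was 401 and 383. Without 12 h EtOH replicates 1, 2 or 3 it was 1244, 3922 and 1188. In roots it was 3436 without EtOH replicate 3 of 3 h.

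EtOH libraries of later times were compared with those of 0 h. In them 9450 genes in shoots and 7105 in roots differed from 0 h at some time by a limma F test, and all 14 clock genes did so in both tissues. The 0 h columns were identical to those labelled untreated, so if they hold untreated seedlings, these counts mix time with EtOH. In shoots, CCA1, a morning gene of the clock, stood at 431 ± 32.6 at 0 h, 68.5 ± 8.63 at 1 h, 748 ± 211 at 3 h, 67.7 ± 24.4 at 6 h, 4120 ± 2180 at 12 h and 3120 ± 261 at 24 h (adjusted p = 1.85e-14). TOC1, an evening gene, stood at 361, 1670, 311, 1470, 112 and 136 at those times, and PRR7 at 2380, 2920, 3240, 2410, 830 and 826. Compared with 0 h one time at a time, 12, 0, 12, 12 and 10 of the 14 clock genes differed in shoots at 1, 3, 6, 12 and 24 h, and 11, 4, 10, 12 and 12 in roots. The 0 for shoots at 3 h is by limma, the tool run for this test, with 5 of the 14 at an unadjusted p under 0.05, and was 7 without the libraries under 0.5 M, where the other counts lay within 2 of these.

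**Figure D5:**
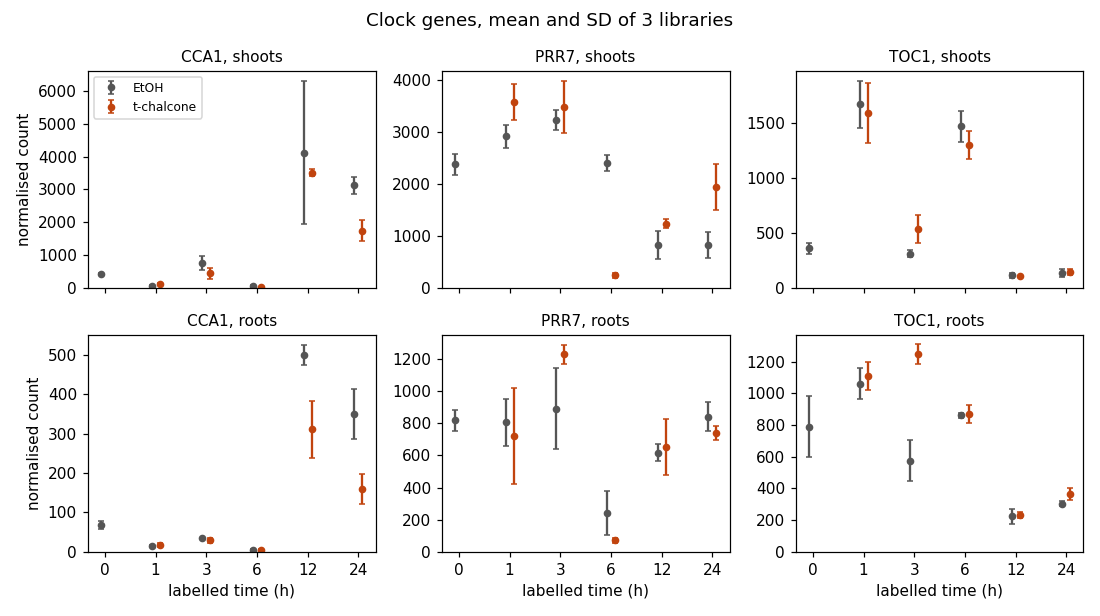
Mean ± SD (n = 3) of the deposited values of the clock genes CCA1, PRR7 and TOC1 over time (x axis, h; y axis linear) in EtOH and t-chalcone libraries of shoots and roots. In shoots CCA1 in EtOH goes from 431 at 0 h to 68.5 at 1 h, 748 at 3 h and 67.7 at 6 h, and PRR7 at 6 h lies at 237 in t-chalcone against 2410 in EtOH libraries.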

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

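Of the tests given here, the 3 on clock and photosynthesis genes of treated plants, the 2 on clock genes of the controls and that of the change after thinning were chosen only after the results were seen, while the splits of the libraries and the 2 other tests on roots at 24 h were set beforehand.

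Clock or photosynthesis genes differed between t-chalcone and EtOH libraries at several times, with photosynthesis genes in shoots at 6 h at a median of -0.84 (range -5.95 to 1.72), while camera passed neither list in shoots at 24 h or in roots at 1, 3, 12 and 24 h. Root tissue mixed into the treated shoot libraries would raise root markers, but their median there was -0.33 over 12 genes (range -0.86 to 1.03), which argues against it. A hypothesis left open is that treated plates stood at another point of the daily cycle than their controls. Across the 14 clock genes, not independent replicates, the 3 h effect was set against control values at 6 h minus 0 h. Effects at 12 and 24 h were set against 0 h minus 24 h and 0 h minus 12 h. Pearson r was 0.98, 0.22 and 0.89 in shoots and 0.75, 0.61 and 0.93 in roots. The 0.22 was 0.69 without the libraries under 0.5 M. By the labels 0 h and 24 h are the same hour, so 12 h was no test of a later point. Plates harvested at a different hour would move shoots and roots together: across the same genes, shoot and root effects had an r of 0.17, 0.92, 0.66, 0.17 and 0.65 at 1, 3, 6, 12 and 24 h, and the 0.17 at 12 h was 0.75 without shoots EtOH replicate 2, the library of that time under 0.5 M. Hour of harvest and treatment are confounded in these labels, so an effect of t-chalcone on the clock itself stays open and was not tested.

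In roots at 24 h, 366 of the 378 genes past the threshold were lower, and all 3 t-chalcone libraries carried S numbers while all 3 controls did not. The library batch is a candidate explanation: across the 378 genes, the difference between S-number and other libraries within the 12 h groups, where the S-number libraries held 2.25 and 1.72 M and which share no library with 24 h, followed the 24 h effect at r = 0.53, and at 0.38 across all 19835 genes, which are not independent replicates. With a batch term the median change of the 378 genes went from -0.91 (median SE 0.22) to -0.58 (median SE 0.31), and limma called 0 genes, so the calls ended with a smaller change and a larger error, not with a change of 0. Thinning the controls to 1.61 M left a median of 148.5 calls over 10 draws (133 to 189), but added counting noise removes calls whatever the cause, and the change of the 378 genes was still -0.72 (-0.74 to -0.71 over the draws, median SE 0.22), which argues against depth as the whole cause. An effect of t-chalcone on these genes stays open beside the batch and a part from depth.

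The clock genes of EtOH libraries did not fall as their labelled hours would place them. At 24 h, the same hour of the day as 0 h under the stated light cycle, 10 of 14 clock genes differed from 0 h in shoots and 12 in roots, which argues against a harvest of all groups at the labelled hours of one undisturbed cycle. A candidate explanation for the early times is that labels of 1 h and 3 h were exchanged, since 13 clock genes in shoots and 10 in roots lay closer to 0 h at 3 h than at 1 h (13 and 11 without the libraries under 0.5 M), but 10 falls between the bounds set for and against it. An effect of EtOH or handling on the clock was not tested, because no group without EtOH other than 0 h was analysed here.

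The effect of t-chalcone differed between times for 614 genes in shoots and for 1628 in roots. It differed between tissues for 27 genes at 1 h, 15 at 3 h, 46 at 6 h, 34 at 12 h and 300 at 24 h, where a term for the S number took the count to 32. Values below are log2 fold changes in shoots minus those in roots ± limma standard error. At 1 h they were 2.45 ± 0.52 for CSLC12 (AT4G07960, adjusted p = 0.0255), 2.59 ± 0.55 for FRO4 (0.0279), -3.56 ± 0.80 for NUDT21 (AT1G73540, 0.044) and -4.20 ± 0.94 for RTFL12 (AT4G13395, 0.044). The values at 3 h were 2.03 ± 0.37 for AK3 (AT3G02020, 0.0237), 2.22 ± 0.44 for GSTF14 (0.0329), -2.17 ± 0.48 for PAL4 (AT3G10340, 0.0492) and -2.12 ± 0.47 for RHA2B (AT2G01150, 0.0492). At 6 h, AOC2 had 2.2 ± 0.52 (0.0458), SNRK2-8 (AT1G78290) 1.59 ± 0.37 (0.0358), LHCB2.2 -5.97 ± 0.74 (1.22e-06) and PORA -5.83 ± 0.96 (0.000323). At 12 h, AOC2 and APR3 had 2.62 each (± 0.52 and ± 0.49, adjusted p = 0.0119 and 0.00733), APR1 2.01 ± 0.47 (0.0468) and BT2 -2.28 ± 0.40 (0.00417). The root means of AOC2 at 12 h were 6.25 in EtOH and 5.65 in t-chalcone libraries. At 24 h, BCAT-2 had 3.87 ± 0.79 (0.00486), BCB 3.37 ± 0.65 (0.00254), APR1 -2.2 ± 0.47 (0.00737), DFR -6.75 ± 1.02 (0.000126), LDOX -5.92 ± 1.13 (0.00253) and TT4 -3.78 ± 0.93 (0.0248).

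Other splits of the same libraries were counted for each result. Regrouping 3 against 3 makes 10 splits, too few for a share under 0.05. The real count and the highest of the others were 11 and 0 in shoots at 1 h, 8 and 0 at 3 h, 355 and 0 at 6 h, 174 and 2 at 12 h, and 262 and 273 at 24 h, and in roots 914 and 0, 2688 and 0, 89 and 0, 6 and 6, and 378 and 0 at the same times. In shoots at 24 h the split with 273 set EtOH replicate 1 and t-chalcone replicates 1 and 3 against the rest, which puts both libraries of that time under 0.5 M on one side, and 2 of the 10 splits gave as many calls as the real one. Likewise, 2 of 10 did so in roots at 12 h, where the split with EtOH replicate 1 and t-chalcone replicates 1 and 3 together puts both S-number libraries of that time on one side, and with them the 3 shallowest (1.1 to 2.25 M against 18.1 to 21.0 M). A term for the S number left the count at 6. In the 8 other comparisons 1 of 10 splits, the real one, gave as many.

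For the other results 100 splits were drawn, the real one included. Chance was excluded, at 1 of 100, for effects that differ between times (614 against a highest other of 176 in shoots, 1628 against 502 in roots), for times in controls (9450 against 6295 and 7105 against 4613) and for list tests in shoots (67 against 54, median of the others 36), and at 4 of 100 for list tests in roots (48 against 49, median 30). For differences between tissues chance was not excluded at 1 h (7 of 100, 27 against 131), 3 h (10 of 100, 15 against 214), 6 h (12 of 100, 46 against 218) and 12 h (10 of 100, 34 against 150). At 24 h, 2 of 100 splits gave as many as the real 300, the highest other giving 3646. Splits that call several times the real count point to a structure of these samples, which was not identified.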

How the results depend on the processing

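Of the settings given here, leaving out the 5 libraries under 0.5 M, the filter above the lowest value and edgeR without those libraries were chosen only after the data were seen. No paired analysis was possible because replicate numbers were given in accession order and the groups share no replicate number from the labels. Depth limits the shallow libraries most, where up to 77.8% of genes stand at the lowest value. Of 267 t-chalcone effects on named genes past the threshold, 0 reversed in limma, edgeR or DESeq2 under any setting. Calls were kept for 263 with a pseudocount of 0.5, 253 with TMM, 259 with median-of-ratios, 239 with the S-number term, 205 with array weights, 249 with edgeR and 245 of 260 with DESeq2, and for 249 of 265 without the 5 libraries and 179 of 261 with only the groups of the contrast. Leaving out single libraries kept 1183 of 1602 such calls. For list tests, 67 of 67 passed in shoots under TMM and under median-of-ratios scaling, and in roots 43 and 47 of 48. Where no cause is named below, the cause was not tested.

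Counts that moved by over 1.5 times follow, as genes past the threshold. In shoots at 3 h a pseudocount of 4, a filter of 50 and the filter above the lowest value each gave 16 against 8, and at 12 h the filter of 50 gave 287 against 174. TMM gave 206 in roots at 24 h (11 higher, 195 lower) against 378. Median-of-ratios scaling gave 20 in shoots at 3 h and 12 in roots at 12 h, and 7 genes higher at 1 h in both tissues against 4.

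Array weights gave 588, 8084, 9239, 3251 and 0 genes in shoots at 1, 3, 6, 12 and 24 h and 4722, 445, 1096, 26 and 2858 in roots, against 2442 at an unadjusted p under 0.05 without weights, 533 by edgeR and 580 by DESeq2 for the 0 in shoots at 24 h. They also gave 10930 and 4612 genes (shoots, roots) with effects that differ between times, 17959 and 16683 for times in controls, 1314, 152, 6133, 1562 and 0 for differences between tissues, and overlaps of 144 (roots 1 h and 3 h, lower), 117 (roots 3 h and 6 h, higher) and 120 (shoots and roots at 1 h, higher).

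A term for the S number gave 5 genes in shoots at 1 h and 0 in roots at 24 h, where 749 had an unadjusted p under 0.05 and edgeR without the term gave 361. It gave 733 for times in roots, 32 for tissues at 24 h and 2 for the overlap of tissues at 1 h. Leaving out the S-number libraries gave 5 and 55 in shoots at 1 h and 24 h, 2 in roots at 12 h, 374 for times in shoots, 0 and 9 for tissues at 3 h and 12 h, and 2 for the overlap of tissues.

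Without the 5 libraries under 0.5 M, counts were 92, 1307, 4430, 830 and 2438 in shoots and 1697, 1646, 239, 138 and 2476 in roots. The spread shared by all groups of the tissue is then estimated without those libraries, and fewer genes are tested (19116 of 22884 in shoots, 19272 of 19835 in roots); which of these moved calls at times that hold none of the 5 was not tested. Differences between times numbered 6376 in shoots and 3236 in roots, times in shoot controls 15133, differences between tissues 297, 781, 1351, 212 and 3440, and the overlaps 348 (roots 1 h and 3 h, lower), 104 (roots 3 h and 6 h, higher) and 23 (tissues at 1 h).

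With only the groups of the contrast in the fit, shoots gave 131, 4909 and 0 genes at 3, 6 and 12 h and roots 384, 241 and 0 at 3, 6 and 12 h. For these counts of 0, with fewer libraries behind each spread, edgeR gave 555 and 337, DESeq2 1254 and 86, and limma with all groups 6853 and 1525 at an unadjusted p under 0.05. The same setting gave 5663 and 4619 for times in controls of shoots and roots, 2541 for times in roots, 146, 0, 1998 and 0 for tissues at 1, 3, 6 and 12 h, and overlaps of 134 and 80 for genes higher and lower in roots at 1 h and 3 h. For the counts of 0 between tissues under these settings, all by limma, the tool run there, the fit of all groups gave 3728, 5792 and 2858 genes at an unadjusted p under 0.05 at 3, 12 and 24 h.

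With edgeR, counts were 181, 294, 2756, 555 and 533 in shoots and 2789, 269 and 337 in roots at 1, 6 and 12 h, with overlaps of 531 and 570 (roots 1 h and 3 h, higher and lower), 126 (roots 3 h and 6 h) and 25 (tissues at 1 h). Without the 5 libraries edgeR gave 248, 645, 5530, 1432 and 1680 in shoots, 2896, 230 and 348 in roots and overlaps of 549, 553, 102 and 38. DESeq2 gave 112, 170, 2070, 1254 and 580 in shoots, 1875, 1779, 208 and 86 in roots at 1, 3, 6 and 12 h, and overlaps of 408, 368, 105 and 20. With an estimated correlation, camera passed 21 lists in shoots (11 higher, 10 lower) and 9 in roots (6 higher, 3 lower).

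Leaving out single libraries gave, from lowest to highest, 1 to 58, 3 to 80, 168 to 265, 22 to 8935 and 94 to 513 genes in shoots and 522 to 837, 1028 to 5427, 13 to 90, 2 to 32 and 31 to 362 in roots. The ranges were 383 to 3922 and 1103 to 3436 for effects that differ between times (shoots, roots), 7737 to 14105 and 5919 to 9294 for times in controls, 62 to 72 and 44 to 54 for list tests, and 10 to 101, 0 to 760, 24 to 47, 5 to 7317 and 95 to 843 for tissues. For overlaps they were 174 to 238 and 129 to 215 (roots 1 h and 3 h, higher and lower), 9 to 56 (roots 3 h and 6 h) and 1 to 6 (tissues at 1 h).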

Other observations

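The comparison of libraries by similarity was added after the data were seen, while the list tests and the rule for genes were fixed beforehand, and values are given without explanation.

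Cell wall genes moved in both directions in roots. At 1 h, 4 of 16 fell, including the expansins EXPA18 (AT1G62980, -1.83 ± 0.28, adjusted p = 3.72e-05 by limma) and EXPA7 (AT1G12560, -1.66 ± 0.32), 2 rose, with EXPA10 (AT1G26770) at 1.63 ± 0.30, and 10 did not pass (10 adjusted over the list alone, camera adjusted p = 0.114). Redox genes rose in 5 of 24 cases at 1 h, with the dehydroascorbate reductase DHAR2 (AT1G75270) at 1.24 ± 0.21 and the alternative NADH dehydrogenase NDB2 (AT4G05020) at 1.00 ± 0.15, and 19 did not pass (5 adjusted over the list alone, camera adjusted p = 0.000859, adjusted p = 0.334 with an estimated correlation). Of 16 iron genes in roots at 1 h, 4 rose, including BHLH101 (AT5G04150, 1.43 ± 0.40) and BTS (AT3G18290, 0.89 ± 0.19), 2 fell, with FRO2 at -1.48 ± 0.41, and 10 did not pass, at a median of -0.13 and a mean of 0.04 (6 adjusted over the list alone, camera adjusted p = 0.446).

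Libraries did not always sit closest to their own group. By Spearman correlation across genes, which are not independent replicates, 10 libraries were most similar to one outside their group, among them shoots EtOH 1 h replicate 3 with t-chalcone 1 h replicate 3 (rho 0.984) and roots EtOH 24 h replicate 3 with roots t-chalcone 12 h replicate 2 (rho 0.970). All 3 t-chalcone root libraries of 12 h were closest to EtOH libraries of 12 or 24 h.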
